A study of Mus musculus with 94 samples.

How the data were processed

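Kidney and liver RNA of C57BL/6 mice with a human APOL1 transgene (G0 or G1) was sequenced as QuantSeq 3′ libraries, 47 of kidney and 47 of liver from 47 animal codes. Groups were taken from the genotype, ASO, challenge and tissue labels. For the animal with code K1 the title and the ASO label name the control ASO, while the letter of its code is that of the APOL1 ASO group. It was left out, and was added to either group as an alternative. The submitters' processing notes name bcl2fastq 2.17.1.14, Salmon 0.7.2 and the build GRCm38.p4. The deposited files hold expected counts, that is, estimated counts of reads per mouse transcript as Salmon gives them, without normalization by the authors. Their further column is headed TPM but holds RPM, reads scaled to library size without a length correction, the deposited value differing from RPM by at most 4.4e-10, and was not used here. The annotation release, trimming and strand setting are not given in the sources used here.

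Estimated reads were summed per gene over the 90712 of 92468 transcripts (98.1%) found in GENCODE M21 (GRCm38), rounded, and gave 31114 genes. The unmatched 1756 transcripts held 0.612 to 1.38% of a library's reads. Reads that fit several genes are shared out by Salmon, so that values of close paralogs are uncertain. Detected genes per library were 13699 to 16242 in kidney and 11535 to 15586 in liver, mitochondrial genes took 3.73 to 11.2% and 2.29 to 8.62% of reads, and the 10 most abundant genes 8.98 to 17.5% and 9.82 to 22.0%. No pair of libraries within a group was identical (0 of 66 pairs in kidney and 0 of 66 in liver). The reads carry no molecular identifiers, so that floors from counts of 0 cover counting error only.

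Each tissue was fitted as 12 groups over 46 libraries (34 residual degrees of freedom) with the edgeR (4.0.16) quasi-likelihood test, robust, after filterByExpr and TMM normalization, and the Benjamini-Hochberg adjusted p was held against 0.05. The tissue difference was fitted over both tissues together. Genes tested numbered 14938 in kidney, 13952 in liver and 15344 over both. The biological coefficient of variation was 0.51 in kidney and 0.55 in liver. Fold changes are log2 with their standard error, and CPM values are TMM-normalised. The contrasts were the IFN-γ response in G0 and in G1 vehicle mice and its difference, G1 against G0 without IFN-γ, control ASO against vehicle and APOL1 ASO against control ASO over genotypes and challenges, APOL1 ASO against control ASO in G1 mice with IFN-γ, the difference of the IFN-γ responses under these ASOs, and the IFN-γ response in kidney minus that in liver. 35 gene lists of pathways and cell types were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated one. Of 106 list calls at the preset value 27 held with the estimate. These contrasts, the lists, the alternatives called planned below and the rule for named genes were fixed before the data were examined. That rule takes, among genes past the threshold with a mean log2 CPM of at least 1 and without predicted models, the 10 largest rises and falls, up to 4 members of each list with a gene past the threshold, and always the mouse Apol genes, Cxcl9, Havcr1, Lcn2 and Nphs1. Some genes that this rule takes are not reported here.

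Replicate numbers do not pair libraries of different groups: deviations of libraries with the same number correlated at a mean r of 0.001 in kidney and 0.013 in liver. Kidney and liver with the same code come from the same animal, and their deviations correlated at a mean r of -0.004 (-0.423 to 0.494 over 46 animals), so the tissue difference is given without and with the animal as a block. Alternatives planned beforehand were relative log expression (RLE) size factors, DESeq2 (1.42.0), no low-count filter, a block, the compared groups alone in the model, each library left out in turn and K1 in either group. Added after seeing the data were the removal of libraries under 2 M reads, the first component of the libraries' deviations from their group means as a covariate, limma-voom with sample quality weights, the IFN-γ response within each ASO arm, and contrasts pooled over 6 arms.

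Sensitivity was tested on simulated counts, drawn gene by gene from negative binomial distributions. The draws used the mean shares and dispersions of the real genes and the real library sizes, with 200 genes changed by a factor of 2, 4 or 8. They lack the deviations that genes of a real library share, so that recovery and false calls may differ in the real data. For the IFN-γ response in G1 kidneys the edgeR test recovered 5.97, 56.7 and 89.4% of genes at these folds, with 2.88% false calls, and in G1 livers 1.49, 52.2 and 69.7%, with 5.75%. DESeq2 gave 12.9 and 16.8% false calls. Doublings of single genes between groups of 4 were thus mostly out of reach. Computations ran in R 4.3.3 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).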

Results

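Gene expression was measured in kidney and liver of C57BL/6 mice that carried a human APOL1 transgene, either the reference allele G0 or the kidney-risk allele G1. APOL1 encodes a secreted trypanolytic apolipoprotein that mice lack, and interferon-γ (IFN-γ) raises its transcription in human cells. Per the labels' protocols, mice received vehicle (PBS), a control antisense oligonucleotide (ASO) without a target, or an ASO against APOL1, at 50 mg/kg weekly over 4 weeks. On the following day they were given PBS or IFN-γ, and the tissues were taken 48 hours afterwards. Libraries were made by QuantSeq, which reads the 3′ end of each polyadenylated RNA. The 2 genotypes, 3 dosing arms and 2 challenges made 12 groups per tissue, each of 4 mice, except that G1 mice given PBS after control ASO or after APOL1 ASO were 3 each. In all, 47 mice gave 94 libraries, and 46 per tissue were compared, because the title of 1 mouse names the control ASO and its animal code belongs to the APOL1 ASO group.

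Kidney libraries held 1.44 to 20.04 M reads (median 7.32) and liver libraries 0.66 to 17.47 M (median 5.32). Under 2 M reads were 1 kidney library (G0, control ASO, IFN-γ, replicate 2) and 5 liver libraries, each in a different group but mostly of G1 mice. In G0 this was control ASO PBS replicate 3. In G1 they were vehicle PBS replicate 3, control ASO IFN-γ replicate 3, APOL1 ASO PBS replicate 4 and APOL1 ASO IFN-γ replicate 4. At these depths the median standard error of a log2 fold change between vehicle groups was 0.48 in kidney and 0.55 in liver, so that small changes were not detectable gene by gene. The transcripts counted were mouse transcripts, with 0 human ones among them, so that human APOL1 RNA and its knockdown by the ASO are not analysed here. Reads of the Y-chromosome genes Kdm5d and Uty were found in all 94 libraries, from 11.7 to 107.7 CPM (reads scaled to library size) summed. Values after ± are standard errors beside log2 fold changes and standard deviations beside CPM.

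The IFN-γ challenge in vehicle-dosed mice asked what the cytokine does to each tissue. In G0 kidneys (n = 4 per group), IFN-γ raised the interferon-inducible GTPases that guard against intracellular parasites and the machinery of antigen presentation. Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, GRCm38), a GTPase that attacks parasite vacuoles, went from 18.6 ± 4.14 to 414 ± 138 CPM, a log2 fold change of 4.48 ± 0.45 (adjusted p = 7.51e-09). The related Gbp6 (4.40 ± 0.52), Igtp (4.39 ± 0.62) and Irgm1 (2.87 ± 0.38) rose with it, as did Ubd (4.19 ± 0.67), a ubiquitin-like modifier. Tgtp1, another such GTPase, had 0 reads in the PBS kidneys and 725 to 1906 per library after IFN-γ. Against a floor of 3 counts over the PBS group, which covers counting error only, that is at least 892-fold higher. Reads that fit both Tgtp1 and its paralog Tgtp2 are shared out by Salmon, so that the 0 and this fold are uncertain. For class I presentation, the immunoproteasome subunit Psmb8 (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454) rose by 3.79 ± 0.32 (adjusted p = 1.38e-10), the peptide transporter Tap1 by 3.83 ± 0.64 and the light chain B2m by 3.57 ± 0.50. For class II presentation, the chain H2-Ab1 rose by 3.65 ± 0.46, the peptide exchangers H2-DMa and H2-DMb1 by 3.60 ± 0.43 and 2.65 ± 0.26, and the invariant chain Cd74 by 3.30 ± 0.44. Complement genes C4b (2.41 ± 0.31), C2 (1.63 ± 0.27) and C1ra (1.60 ± 0.33) rose as well, and so did Il18bp (3.04 ± 0.67), which binds and blocks interleukin-18, and Aif1 (1.96 ± 0.38), a macrophage marker.

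The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 47 genes up and 7 down in G0 kidneys among 14938 tested. Of 33 measured genes of the IFN-γ response list, 10 rose over all genes tested, and 20 rose and 1 fell when adjusted over the list alone (median log2 fold change 2.26, the same with Tgtp1 at its bound). The gene that fell was Pim1, a kinase named after its values were seen, at -0.93. For the MHC class I list the counts were 8 and, adjusted over the list alone, 13 of 23 (median 1.87), for MHC class II 7 and 9 of 11 (2.65), and for type I interferon genes 4 and 9 of 29 (1.07). These 4 lists passed camera, a test of a list against all other genes, with adjusted p = 2.6e-37, 2.12e-35, 1.96e-44 and 2.3e-11, and also with an estimated correlation among genes. Macrophage markers moved with them: the macrophage list rose (median 1.01, adjusted p = 8.08e-07, and 0.0012 with an estimated correlation). The cell cycle list rose too (median 0.62, 0.00358 with an estimated correlation), with the survivin gene Birc5 at 1.71 ± 0.40. The podocyte list (median -0.44, camera adjusted p = 0.0189) and the complement list (0.13, 0.0162) lost their calls, with adjusted p = 0.0965 and 0.295 with an estimated correlation, as did the chemokine list (0.49, 0.00229, then 0.117) and the lysosome list (0.44, 0.00129, then 0.15). Cxcl9 (-0.63 ± 0.45, adjusted p = 0.625), a T-cell chemokine, and the tubular injury markers Havcr1 (1.76 ± 0.71, 0.306) and Lcn2 (1.56 ± 0.73, 0.394) did not pass. The calls of falls depended on single libraries: edgeR called 42 genes up and 0 down without replicate 4 of the PBS group, and 44 and 47 up and 0 down without replicate 1 or 2 of the IFN-γ group. Without that PBS library Xpo1, the nuclear exporter, went from -3.20 to -0.35, mt-Nd4l from -2.69 to -0.36, mt-Nd5 from -2.30 to -1.04, St6galnac6 from -1.93 to -0.19 and Eci3 from -1.48 to -0.45, all short of the test. Without IFN-γ replicate 1 or 2 these 5 lost their calls at folds near those with all libraries, such as -3.16 and -3.15 for Xpo1. Without IFN-γ replicate 3 all 5 calls were lost too, and without replicate 4 those of mt-Nd4l, St6galnac6 and Eci3. Il18bp was no longer called with PBS replicate 1, 2 or 4 left out, and Birc5 with PBS replicate 2 or 4 or IFN-γ replicate 1, 3 or 4 left out. Falls outnumbered rises among the 177 genes called without replicate 3 of the PBS group (69 up, 108 down) and the 205 called by DESeq2 (83 up, 122 down). The number was 13 (13 up, 0 down) with the compared groups alone in the model and 182 (123 up, 59 down) with the first component of the libraries' deviations as a covariate.

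In G1 kidneys (n = 4 per group) IFN-γ raised the same families. Iigp1 went from 34.7 ± 4.55 to 407 ± 172 CPM (3.55 ± 0.43, adjusted p = 7.85e-07), Ubd rose by 4.40 ± 0.67, Gbp6 by 3.91 ± 0.51 and Gbp3 by 3.21 ± 0.46. Tgtp1 again had 0 reads after PBS and was at least 713-fold higher after IFN-γ against the same floor, with the same uncertainty from its paralog. Psmb8 (3.35 ± 0.32), B2m (3.15 ± 0.49), the class I chain H2-K1 (2.85 ± 0.45) and the class II genes H2-DMb2 (4.09 ± 0.49) and H2-Ab1 (2.42 ± 0.44) rose, as did Cxcl10 (3.36 ± 0.51), which attracts T cells, C4b (2.21 ± 0.30) and Il18bp (3.10 ± 0.67). Scd1, the stearoyl-CoA desaturase of fatty acid synthesis, fell (-1.73 ± 0.36, adjusted p = 0.0123), and so did the carboxylesterase Ces1e (-1.41 ± 0.33, 0.0398). In G1 kidneys 34 genes were called up and 2 down by edgeR after Benjamini-Hochberg adjustment. Of the IFN-γ list 11 genes rose over all genes and 23 adjusted over the list alone (median 2.23), of MHC class I 8 and 16 (1.79), of MHC class II 6 and 7 (1.95) and of type I interferon genes 3 and 9 (1.06). These lists passed camera with and without an estimated correlation (IFN-γ list adjusted p = 9.64e-63 and 1.93e-11). Red blood cell markers fell alongside (median -1.44, camera adjusted p = 1.82e-09, and 0.014 with an estimated correlation). The macrophage list (median 0.35, camera adjusted p = 0.0056) and the fatty acid synthesis list (-0.28, 0.0207) lost their calls, with adjusted p = 0.067 and 0.0756 with an estimated correlation. Cxcl9 was 1.42 ± 0.45 (adjusted p = 0.527, 0.00667 adjusted over the list alone), and Lcn2 1.69 ± 0.70 (adjusted p = 1). Havcr1 stood at 3.69 ± 3.99 CPM after PBS and 10.6 ± 5.27 after IFN-γ (adjusted p = 1). Scd1 was no longer called with IFN-γ replicate 1 or 2 or PBS replicate 2 left out, Ces1e with IFN-γ replicate 1 or 4 or PBS replicate 1 or 2, Il18bp with PBS replicate 2, 3 or 4 and Tgtp1 with PBS replicate 2 or 3. DESeq2 called 69 genes (50 up, 19 down) and limma-voom with sample quality weights 72 (63 up, 9 down).

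Whether the kidney response differed by APOL1 genotype was tested as the difference of the G1 and G0 responses. The G0 and G1 responses, which share no libraries, had 29 raised genes in common, where chance gives 0.107, and 52 of the 54 genes called in G0 and 36 of the 36 called in G1 had the same sign in the other genotype. Across all 14938 genes, which are not independent replicates, the fold changes correlated at r = 0.086 (Spearman's rho 0.075). The difference for Havcr1 was -0.26 ± 0.93 (adjusted p = 0.99) and for Cxcl9 2.06 ± 0.63 (0.712, and 0.077 adjusted over the list alone). For this difference edgeR called 0 genes, with 1007 at an unadjusted p under 0.05, and DESeq2 8 up and 8 down. The MHC class II list (median -0.76) and the red blood cell list (-1.48) passed camera with adjusted p = 0.00101 and 2.52e-05, but had adjusted p = 0.166 and 0.166 with an estimated correlation. The IFN-γ response was also present in the ASO arms, a comparison chosen after the data were seen. In kidney the mean log2 CPM of the IFN-γ list was higher after IFN-γ than after PBS by 2.20 ± 0.18 with vehicle, 2.10 ± 0.18 with control ASO and 2.04 ± 0.18 with APOL1 ASO in G0 mice. In G1 mice these differences were 2.12 ± 0.18, 1.67 ± 0.19 and 2.05 ± 0.19. Genes called up and down were 38 and 1 with control ASO and 47 and 1 with APOL1 ASO in G0 kidneys, and 30 and 3, and 32 and 3, in G1 kidneys.

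**Figure D1:**
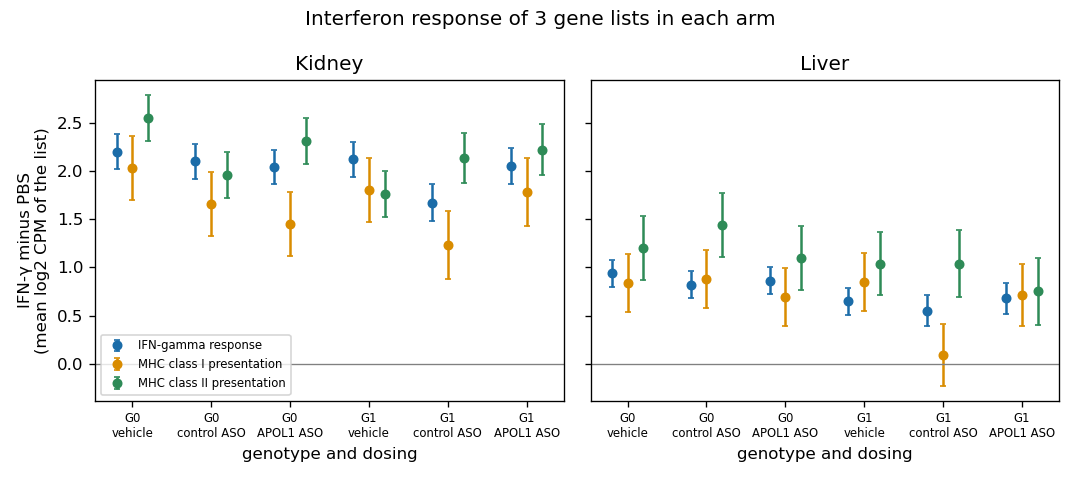
Difference in mean log2 CPM between IFN-γ and PBS (vertical axis) for the IFN-γ response, MHC class I and MHC class II lists in each genotype and dosing arm of kidney and liver, with points for the difference and bars for its standard error. In kidney the IFN-γ list lies between 1.67 and 2.20 in the 6 arms, and in liver between 0.55 and 0.94.

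In liver the same challenge moved few single genes, while the interferon lists rose. In G0 livers (n = 4 per group) the class II chain H2-Aa rose by 2.20 ± 0.43 (adjusted p = 0.0486), and Cxcl9 was 1.89 ± 0.46 (0.348, and 0.00523 adjusted over the list alone), from 20.1 ± 5.87 to 74.6 ± 32.5 CPM. Tead3, a transcription factor of the Hippo pathway, had 39 to 71 reads per library after PBS and 0 after IFN-γ. That is at least 77.1-fold lower against a floor of 3 counts over the group, which covers counting error only. In G0 livers with control ASO or APOL1 ASO 0 genes were called down after IFN-γ, so Tead3 was not called there. Nor was it called in G1 livers with vehicle. In G1 livers Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase apolipoprotein, went from 5.66 ± 5.53 to 92.9 ± 26.6 CPM (3.91 ± 0.67, adjusted p = 0.00797), and the adenosine A1 receptor gene Adora1 (-2.26 ± 0.42, 0.0151) and Lipc (-1.99 ± 0.37, 0.0151), the hepatic lipase, fell. Cxcl9 was 1.74 ± 0.46 in G1 (0.241, and 0.0133 adjusted over the list alone). The IFN-γ list rose in G0 (median 0.92, 5 genes adjusted over the list alone, camera adjusted p = 1.04e-15) and G1 (0.33, 2 genes, 0.00466), as did MHC class I (medians 0.87 and 0.74) and MHC class II (1.5 and 1.08). With an estimated correlation these calls held, with adjusted p = 1.49e-07 and 0.0445 for the IFN-γ list, and type I interferon genes rose in G0 (median 0.71, 0.000713) but had a median of 0.00 in G1 (camera adjusted p = 0.429). Red blood cell markers fell in G1 livers (median -1.14, 0.0445 with an estimated correlation), while macrophage markers in G0 (0.50) and G1 (0.56), and the acute-phase list in G1 (0.65), lost camera's call, with adjusted p = 0.142, 0.213 and 0.54 with an estimated correlation.

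In single-gene tests of liver, edgeR called 1 gene up and 1 down in G0 livers and 1 up and 2 down in G1 livers after Benjamini-Hochberg adjustment. DESeq2 called 14 genes (12 up, 2 down) in G0 and 55 (34 up, 21 down) in G1. The counts were 18 (16 up, 2 down) and 12 (4 up, 8 down) without the 5 shallow livers, and 12 (11 up, 1 down) and 137 (109 up, 28 down) with the component as a covariate. The call of H2-Aa was lost with any single library of its groups left out, and that of Tead3 with any of the IFN-γ livers left out. Adora1 was -1.50 and no longer called without replicate 1 of the G1 PBS group, where 6 genes passed (5 up, 1 down), and Adora1 and Lipc lost their calls without replicate 1, 2 or 4 of the G1 IFN-γ group, which left 1 gene, Saa3. Lipc was -1.80 and no longer called without replicate 2 of the G1 PBS group. For the difference of the G1 and G0 responses in liver, edgeR called 0 genes, with 657 at an unadjusted p under 0.05 and 3 up and 1 down by DESeq2. The count was 1 without replicate 2 of the G1 PBS livers. Cxcl9 differed by -0.15 ± 0.62 (adjusted p = 1). The IFN-γ list had a median difference of -0.43 (camera adjusted p = 0.0214, but adjusted p = 0.358 with an estimated correlation). In the ASO arms, Cxcl9 rose after IFN-γ in livers of G1 mice with control ASO (4.35 ± 0.57, adjusted p = 2e-05) and APOL1 ASO (4.39 ± 0.58, 2.12e-05). It also rose in G0 mice with APOL1 ASO (2.79 ± 0.48, 0.00735), and was 1.36 ± 0.47 in G0 mice with control ASO (0.482).

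The difference between the tissues was tested directly, over vehicle-dosed mice of both genotypes (n = 8 per challenge and tissue). Kidney exceeded liver in the response of Iigp1 by 4.06 ± 0.37 (adjusted p = 3.62e-13). The gene stood at 411 ± 116 CPM in G0 livers given PBS and 475 ± 99.0 in those given IFN-γ. The first value is near that of G0 kidneys after IFN-γ, although CPM were normalised within each tissue and levels were not tested between them. Psmb8 (2.58 ± 0.36), H2-DMb2 (3.63 ± 0.55), Gbp6 (3.34 ± 0.60), Cxcl10 (2.54 ± 0.49) and C4b (1.98 ± 0.36) also responded more in kidney, as did Serpina10 (2.70 ± 0.38), an inhibitor of coagulation factor Xa. Hmox1 (-2.62 ± 0.55, adjusted p = 0.0101), which degrades haem, differed the other way, at -1.70 ± 0.61 and -2.27 ± 0.62 in G0 and G1 kidneys and 0.60 ± 0.45 and 0.77 ± 0.45 in G0 and G1 livers, none of these called alone. The difference was -2.08 and not called without replicate 1 of the G1 PBS kidneys. Cxcl9 differed by -1.37 ± 0.44 toward liver (adjusted p = 0.374, and 0.00748 adjusted over the list alone). Between tissues edgeR called 22 genes with the larger value in kidney and 4 with the larger value in liver, and DESeq2 called 32 and 15. With kidney and liver of each animal blocked together the counts were 10 and 1, while the adjusted p given here are without that block. Of 15 called genes taken by the naming rule, 10 kept the call under every alternative other than leaving out single libraries, and 5 lost it under some. All 4 interferon and MHC lists were higher in the kidney response (medians 1.61, 1.27, 0.82 and 0.69 for IFN-γ, class I, class II and type I genes), with 7, 4, 1 and 1 genes over all genes and 13, 11, 4 and 3 adjusted over the list alone. Each held in camera with an estimated correlation (adjusted p = 2.31e-12, 2.52e-06, 0.00223 and 0.000105).

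G1 and G0 mice without IFN-γ were compared in the vehicle arm (n = 4 per group), a contrast that does not separate the risk allele from the transgenic line. In kidney Havcr1 was 1.75 ± 0.72 (adjusted p = 0.55) and Lcn2 1.19 ± 0.74 (0.795), and the slit-diaphragm gene Nphs1 of podocytes was -1.83 ± 0.84 (0.613). Between these kidneys edgeR called 0 genes, with 1136 at an unadjusted p under 0.05, and DESeq2 5 up and 41 down. Without replicate 2 or replicate 3 of the G0 PBS kidneys 4 and 5 genes were called. The kidney injury list (median 0.43, 17 of 23 genes positive, camera adjusted p = 0.0027), MHC class II (0.55, 6.58e-05), podocyte (-0.38, 0.0171), macrophage (0.52, 0.0171) and red blood cell lists (0.62, 0.0281) lost their calls, with adjusted p = 0.0764, 0.0835, 0.123, 0.188 and 0.379 with an estimated correlation.

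In liver the genotypes differed without IFN-γ. Cytochrome P450 genes of drug, steroid and fatty acid oxidation were lower in G1. Cyp2c50 (ENSMUSG00000054827, chromosome 19, 40089688 to 40113950) stood at 124 ± 34.5 CPM in G0 and 10.7 ± 10.5 in G1 (-3.50 ± 0.58, adjusted p = 0.00121). Lower with it were Cyp2c38 (-4.09 ± 0.69), Cyp2c54 (-3.34 ± 0.73), Cyp2f2 (-1.93 ± 0.37) and Cyp2b13 (-4.94). Other genes lower in G1 were Mug1 (-2.27 ± 0.30, adjusted p = 2.57e-05), a plasma protease inhibitor, Serpinb1a (-4.26 ± 0.67, 0.000637), an inhibitor of neutrophil proteases, Elovl3 (-4.22 ± 0.78), a fatty acid elongase, the sulfotransferase Sult2a7 (-4.37 ± 0.90) and Mup3 (-2.54 ± 0.53), a major urinary protein. Higher in G1 were Gpnmb (chromosome 6, 49036546 to 49070929), a glycoprotein of lysosome-rich macrophages, from 1.78 ± 0.594 to 22.2 ± 16.3 CPM (3.68 ± 0.79, adjusted p = 0.0323). Sprr1a (6.65 ± 1.25), a regeneration-associated cornified envelope gene, the adenylate cyclase Adcy1 (3.80 ± 0.81), the adhesion adaptor Nedd9 (2.07 ± 0.43) and γ-actin Actg1 (1.89 ± 0.42) were higher too. The Cyp2c and Mup genes belong to families of close paralogs that share reads, so that the value of each member is uncertain. In G1 livers 6 genes were called up and 10 down by edgeR after Benjamini-Hochberg adjustment. The cytochrome P450 list fell, with 4 of 25 genes over all genes and 8 adjusted over the list alone (median -0.89, camera adjusted p = 1.61e-16, and 0.0113 with an estimated correlation). The sex-biased list fell (0.0186 with an estimated correlation), with 5 of 14 genes adjusted over the list alone but a median of -0.03, and the IFN-γ list rose (median 0.57, 0.0186 with an estimated correlation), with Cxcl9 at 1.35 ± 0.45 (adjusted p = 0.378). The fibrosis list (median 0.57, camera adjusted p = 0.00123) and the p53 target list (0.45, 0.00164) lost their calls, with adjusted p = 0.163 and 0.0991 with an estimated correlation. Of 16 called genes 5 (Serpinb1a, Elovl3, Cyp2c38, Cyp2c50 and Mug1) stayed called with each library left out in turn, and the desaturase Fads3 went from 3.97 ± 0.84 to 1.37 without replicate 3 of the G1 group. The number of called genes was 7 without replicate 2 of the G0 group, 9 without its replicate 1, 3 or 4 and 10 without replicate 1 or 4 of the G1 group. It was 2 (0 up, 2 down) with the compared groups alone in the model and 83 (23 up, 60 down) with the component as a covariate. Rises outnumbered falls among the 43 genes called without the shallow livers (27 up, 16 down), the 84 by DESeq2 (50 up, 34 down) and the 19 without replicate 3 of the G1 group (10 up, 9 down).

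**Figure D2:**
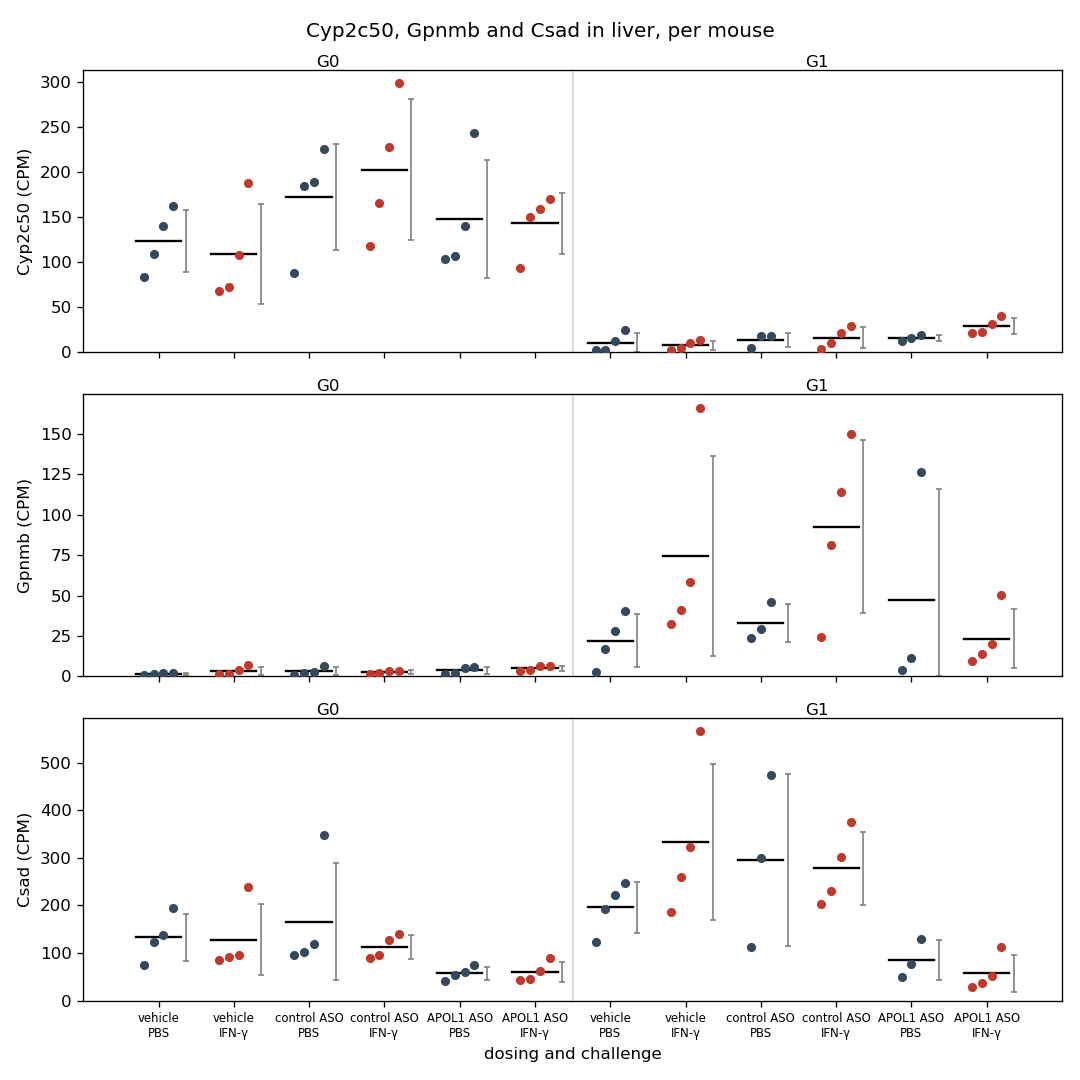
Normalised expression (CPM, vertical axis) of Cyp2c50, Gpnmb and Csad in each liver of the 12 groups, with points for mice, black lines for means and grey bars for the SD beside the points. Group means of Cyp2c50 run from 109 to 203 in G0 and from 7.67 to 29.1 in G1, those of Gpnmb from 1.78 to 5.13 and from 22.2 to 92.6, and those of Csad from 57.6 to 85.5 with APOL1 ASO and from 113 to 295 with control ASO. Csad means with vehicle are plotted but not listed.

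Control ASO was compared with vehicle, averaged over both genotypes and challenges. It sets an oligonucleotide without an APOL1 target against none. Effects of its sequence and of its chemistry cannot be told apart in this contrast. In kidney (n = 15 with control ASO, 16 with vehicle) Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), the master regulator of MHC class II transcription, was lower with control ASO (-2.06 ± 0.35, adjusted p = 0.00504). Ciita stood at 9.88 ± 6.27 and 12.6 ± 12.3 CPM in G0 and G1 mice given vehicle and PBS, and at 2.70 ± 0.983 and 0.405 ± 0.308 with control ASO and PBS. The predicted gene Gm4759, named after its values were seen, fell by 3.90 on the log2 scale. In liver Immp2l (ENSMUSG00000056899, chromosome 12, 41024090 to 41955588), a peptidase of the mitochondrial inner membrane, was lower with control ASO (-2.05 ± 0.26, adjusted p = 8.86e-06), with group means of 3.67 to 10.5 CPM against 12.5 to 33.5 with vehicle, and of 3.73 to 8.30 with APOL1 ASO. For control ASO edgeR called 0 genes up and 2 down in kidney and 0 up and 1 down in liver, with 1877 and 1111 at an unadjusted p under 0.05. DESeq2 called 8 up and 53 down and 19 up and 8 down. The cell cycle list rose in kidney (median 0.46, 3 genes adjusted over the list alone, camera adjusted p = 0.000635, and 0.0248 with an estimated correlation). Red blood cell markers in kidney (median 0.74, camera adjusted p = 3.78e-05) and the cell cycle list in liver (0.51, 0.000358) lost their calls, with adjusted p = 0.148 and 0.378 with an estimated correlation. The kidney count was 901 with the component as a covariate, most of them rises (582 up, 319 down). It was 21 (1 up, 20 down) without replicate 3 of the G0 vehicle PBS group, 9 (1 up, 8 down) without replicate 1 of the G1 vehicle PBS group, 1 by limma-voom and 0 with the mouse of uncertain dosing as control ASO, where Ciita was -1.44. The liver count was 48 by limma-voom, most of them rises (39 up, 9 down), 9 (4 up, 5 down) without the shallow livers, 3 with the covariate and 2 with that mouse as APOL1 ASO. It was 3 without replicate 1 of the G1 vehicle PBS livers. It was 2 with any of these left out: replicate 4 of that group, G0 control ASO PBS replicate 3, G0 vehicle IFN-γ replicate 4, G0 vehicle PBS replicate 3, G1 control ASO IFN-γ replicates 1 and 4, and G1 vehicle IFN-γ replicate 2.

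APOL1 ASO was compared with control ASO, averaged over both genotypes and challenges (n = 15 per dosing in each tissue). Without vehicle, this contrast does not tell a change with APOL1 ASO from an opposite change with control ASO. For control ASO against vehicle only Immp2l was called in liver, which does not exclude such changes. In liver Csad (ENSMUSG00000023044, chromosome 15, 102176999 to 102204724), which makes the taurine precursor hypotaurine, was lower with APOL1 ASO (-1.61 ± 0.24, adjusted p = 0.000385). Csad had lower group means in each of the 4 strata. Also lower were Slc16a6 (-1.13 ± 0.22), a ketone body transporter, Cmah (-1.49 ± 0.30), which hydroxylates sialic acid, Arhgap30 (-1.89 ± 0.33), a GTPase-activating protein, and the zinc-finger gene Zfp652 (-1.36 ± 0.24). Adora1 (1.16 ± 0.21, adjusted p = 0.00473) was higher. Fgf21, a hormone of the fasting liver, was -3.76 ± 0.73 (0.0139), with 27.9 ± 25.3 CPM (n = 3) in G1 livers given control ASO and PBS and means of at most 3.48 in the other groups. For APOL1 ASO edgeR called 2 genes up and 7 down in liver after Benjamini-Hochberg adjustment. No list kept its call with an estimated correlation: type I interferon genes had a median of 0.28 (camera adjusted p = 0.000474, then adjusted p = 0.134) and fibrosis genes -0.17 (0.009, then 0.402). Mouse Apol10b was 1.65 ± 0.55 (adjusted p = 0.415, and 0.026 adjusted over the list of mouse Apol genes alone). Cmah and Fgf21 lost their calls without replicate 2 of the G1 APOL1 ASO PBS livers. Without replicate 3 of the G1 APOL1 ASO PBS livers 14 genes were called. The liver count was 60 (25 up, 35 down) by DESeq2, 68 (37 up, 31 down) by limma-voom, 36 (19 up, 17 down) with the covariate and 15 (5 up, 10 down) without the shallow livers. In kidney edgeR called 0 genes, with 1161 at an unadjusted p under 0.05, and DESeq2 7 up and 6 down, while 366 genes (93 up, 273 down) passed with the covariate and 1 without G0 control ASO PBS replicate 2 or G1 APOL1 ASO PBS replicate 2. Havcr1 was 0.07 ± 0.35 in kidney and Lcn2 -0.75 ± 0.37, with adjusted p = 0.972 and 0.638. The red blood cell list had a median of -0.51 (camera adjusted p = 0.0021, but adjusted p = 0.322 with an estimated correlation).

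Among G1 mice challenged with IFN-γ, which combine the kidney-risk allele with the cytokine, APOL1 ASO was compared with control ASO (n = 4 per group). In kidney Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), which encodes the injury marker NGAL, stood at 22.1 ± 4.64 CPM with control ASO and 4.60 ± 3.30 with APOL1 ASO, and the ranges did not overlap (15.6 to 25.9 against 1.72 to 9.32). Its log2 fold change was -2.28 ± 0.69, with adjusted p = 1 over all genes and 0.0466 adjusted over the list alone. Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), which encodes the tubular injury marker KIM-1, stood at 31.6 ± 16.1 and 16.8 ± 10.4 CPM (-0.92 ± 0.63, adjusted p = 1), against 10.6 ± 5.27 in G1 mice with vehicle and IFN-γ. Aacs (chromosome 5, 125475814 to 125517410), the acetoacetyl-CoA synthetase that feeds ketone bodies into lipid synthesis, was lower with APOL1 ASO, 9.24 ± 2.06 against 26.3 ± 5.08 CPM (-1.50 ± 0.26, adjusted p = 0.0158). Cxcl9 was 0.10 ± 0.44 (adjusted p = 1). Within these kidneys edgeR called 0 genes up and 1 down after Benjamini-Hochberg adjustment, with 737 at an unadjusted p under 0.05 and 4 up and 7 down by DESeq2. Aacs lost its call without replicate 1, 3 or 4 of the APOL1 ASO group or replicate 1, 2 or 3 of the control ASO group, and with the compared groups alone in the model. The kidney injury list (median -0.18, 1 gene lower adjusted over the list alone, camera adjusted p = 0.0125), fibrosis (-0.49, 0.00167) and red blood cell lists (-1.05, 2.29e-06) passed camera but had adjusted p = 0.0958, 0.0958 and 0.0958 with an estimated correlation.

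**Figure D3:**
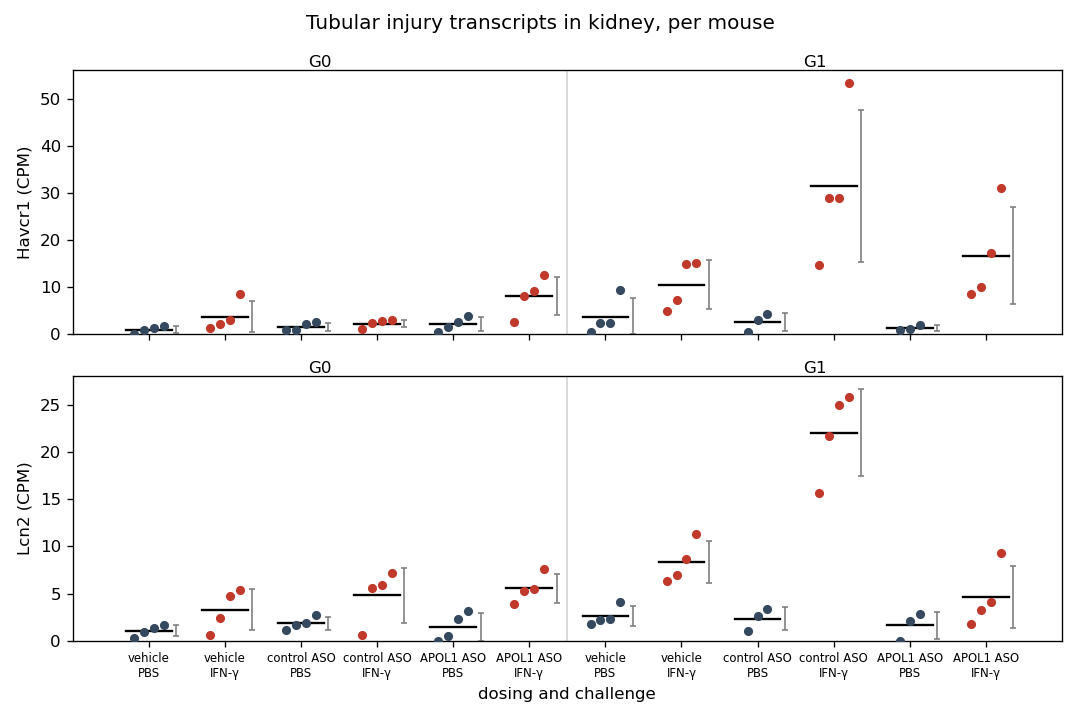
Normalised expression (CPM, vertical axis) of Havcr1 and Lcn2 in each kidney of the 12 groups, with points for mice, black lines for means and grey bars for the SD beside the points, truncated at 0. The highest means are those of G1 mice with control ASO and IFN-γ, 31.6 CPM for Havcr1 and 22.1 for Lcn2.

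In livers of the same mice edgeR called 0 genes between APOL1 ASO and control ASO, with 791 at an unadjusted p under 0.05 and 7 up and 14 down by DESeq2. Cxcl9 stood at 594 ± 134 CPM with control ASO and 559 ± 259 with APOL1 ASO (-0.09 ± 0.44, adjusted p = 0.995). The count was 7 with the component as a covariate, 2 by limma-voom and 1 without replicate 1 of the APOL1 ASO group. The cell cycle list (median -1.14, camera adjusted p = 9.46e-06) and the cytochrome P450 list (0.63, 0.000126) lost their calls, with adjusted p = 0.31 and 0.396 with an estimated correlation. Whether APOL1 ASO changed the IFN-γ response itself in G1 mice was tested as the difference of the responses with APOL1 ASO and with control ASO. Lcn2 in kidney differed by -1.78 ± 1.07 (adjusted p = 1) and Havcr1 by 0.08 ± 0.92. The test of that difference by edgeR called 0 genes in kidney and 0 in liver, with 473 and 870 at an unadjusted p under 0.05. DESeq2 called 3 up and 3 down in kidney and 3 up and 9 down in liver. The red blood cell list in kidney (median -1.85, camera adjusted p = 2.22e-08) and the cell cycle list in liver (-1.54, 0.000762) lost their calls, with adjusted p = 0.0679 and 0.838 with an estimated correlation.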

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

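The tests of kidney read depth and of a state shared by an animal's tissues, and the contrasts pooled over 6 arms, were chosen after the results had been seen. The other tests of the component's causes were set before their own results, but after its scores had been seen. The remaining tests of this part were chosen before. Of 90 tests for a single library far from the others, each of 1 measure in a group of 4 libraries, 8 passed Dixon's 95% critical value, where chance gives about 1 in 20. Replicate 2 of the G1 vehicle IFN-γ kidneys had 10.28 M reads against 7.32 to 7.67 in the others. Replicate 4 of the G1 APOL1 ASO IFN-γ livers had 0.82 M against 5.05 to 5.84. Replicate 1 of the G0 APOL1 ASO PBS livers had a summed 1791 CPM of the IFN-γ list against 1073 to 1188, and 108.6 CPM of Lcn2 against 4.35 to 8.72. Replicate 3 of the G1 vehicle PBS livers had 6.661 CPM of Lcn2 against 37.8 to 43.4. On the first component of the libraries' deviations from their group means, replicate 2 of the G1 APOL1 ASO IFN-γ kidneys scored -69.6 against 16.3 to 29.7. In liver replicate 1 of the G0 control ASO IFN-γ group scored 19.1 against -7.6 to -5.4, and replicate 3 of the G0 control ASO PBS group 129.7 against -55.6 to -31. The IFN-γ response of 26 genes differed between kidney and liver, by a test of the difference itself.

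The 5 livers under 2 M reads scored 92.2 to 129.7 on that component (31.8% of the deviations in liver and 28.2% in kidney), where the next liver scored 25.2. Low depth in itself is argued against in liver, since the 5 shallow livers kept the highest scores of all livers after every library was thinned to 0.65 M reads, although score and reads there had rho -0.13 (permutation p = 0.4, 0.6 adjusted) and r -0.28 (p = 0.059, 0.088 adjusted), and -0.46 without the 2 farthest. In kidney depth as part of the cause stays open, as score and reads correlated at Spearman's rho -0.34 (n = 46, permutation p = 0.022, 0.066 adjusted over 3 relations, 95% interval -0.59 to -0.03) and Pearson's r -0.34 (permutation p = 0.02, 0.06 adjusted), and -0.17 without the 2 farthest. Priming at internal runs of A is argued against by the share of genes with such a run, which among the top 500 genes was 0.983 times that of length-matched genes in liver and 1.08 times in kidney, and a state of the animal shared by its tissues by the scores of its kidney and liver, which correlated at rho 0.04 (-0.25 to 0.32, permutation p = 0.77, r = 0.09, p = 0.56, and 0.09 without the 2 farthest). RNA quality and library chemistry may account for the component and stay open, since the sources used here give neither, and no other biological explanation was tested. Ribosomal protein genes took 1.16 to 2.04% of reads in the 5 shallow livers and at least 2.51% in every other liver. In kidney their lowest share, 1.65%, was that of replicate 4 of the G0 vehicle PBS group, which also had the most extreme kidney score (-100.5). What lowered these shares was not tested.

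Other splits of the compared libraries into groups of the same sizes were fitted with the compared groups alone in the model. Parentheses give the splits, the real one included, that called as many genes, then the genes called by the real split against the highest of the others. Chance cannot be excluded for the number of called genes in the kidney IFN-γ response of G0 (2 of 35, 13 against 698) and G1 mice (2 of 35, 28 against 162) or the liver response of G0 mice (4 of 35, 3 against 53). In each of these 3 a split called several times the real number, which points to a structure of the samples. With 0 real calls every split calls as many, so the splits decide nothing on chance for the liver response of G1 mice (35 of 35, 0 against 3), the genotype difference in kidney (35 of 35, 0 against 826), or the difference of G1 and G0 responses in kidney (100 of 100, 0 against 2) and liver (100 of 100, 0 against 2). Nor do they for APOL1 ASO against control ASO in kidney (100 of 100, 0 against 1), in G1 mice with IFN-γ in kidney (35 of 35, 0 against 1) and liver (35 of 35, 0 against 125), or the difference of responses under these ASOs in kidney (100 of 100, 0 against 317) and liver (100 of 100, 0 against 431). The splits with 826, 125, 317 and 431 calls among these also point to a structure of the samples. Few splits called as many genes for the genotype difference in liver (1 of 35, 2 against 1) and control ASO against vehicle in kidney (3 of 100, 2 against 482) and liver (2 of 100, 1 against 1). The same held for APOL1 ASO against control ASO in liver (2 of 100, 11 against 335) and kidney minus liver (1 of 100, 17 against 2). These shares were not adjusted over the comparisons. They do not exclude chance where the real count was 1 or 2 genes, or where another split called far more. For kidney minus liver no other split called as many. These splits exchanged the challenge labels and not the tissues. They argue against chance in the assignment of the challenge, but do not decide whether the difference between tissues is chance. Splits with 482 and 335 calls point to such a structure for control ASO in kidney and APOL1 ASO in liver. Over 6 arms no other split called as many genes for the IFN-γ response in kidney (1 of 60, 324 against 2). Nor did any for the genotype difference in kidney (1 of 60, 14 against 7) and liver (1 of 60, 780 against 1), which argues against chance for these 3 counts. For the IFN-γ response in liver 1 other split called more (2 of 60, 197 against 241).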

How the results depend on the processing

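The alternatives by depth, by the component and by limma-voom were added after the results had been seen, and the others had been planned. Of 17 counts of called genes, 17 stayed within 1.5 times with RLE size factors, 16 without the low-count filter, 16 with a block and 12 with the compared groups alone. The split of the kidney response in G0 was 47 up and 14 down with RLE factors against 47 and 7. The 106 values of named genes, each of a gene in 1 contrast, kept their direction and call in 2067 of 2324 refits. They lost the call in 250, gained it in 7 and reversed in 0. Leaving out the 5 livers under 2 M reads moved 5 of the counts in liver, and whether their depth or another property did so was not tested.

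Counts of called genes moved by over 1.5 times as follows, and the cause was not tested. DESeq2 called 205 for IFN-γ in G0 in kidney, 69 for IFN-γ in G1, 16 for their difference, 46 for genotype, 61 for control ASO, 13 for APOL1 ASO, 11 for APOL1 ASO in G1 with IFN-γ and 6 for the ASO difference of responses. In liver it called 14 for IFN-γ in G0, 55 for IFN-γ in G1, 4 for their difference, 84 for genotype, 27 for control ASO, 60 for APOL1 ASO, 21 for APOL1 ASO in G1 with IFN-γ and 12 for the ASO difference of responses and 47 for kidney minus liver. Without the low-count filter the count was in liver 1 for IFN-γ in G0. With the compared groups alone, whose fits have fewer libraries, counts were in kidney 13 for IFN-γ in G0 and 0 for APOL1 ASO in G1 with IFN-γ, in liver 0 for IFN-γ in G1 and 2 for genotype and 17 for kidney minus liver. Without libraries under 2 M reads they were in liver 18 for IFN-γ in G0, 12 for IFN-γ in G1, 43 for genotype, 9 for control ASO and 15 for APOL1 ASO. With the component as a covariate they were in kidney 182 for IFN-γ in G0, 1 for genotype, 901 for control ASO and 366 for APOL1 ASO. In liver they were 12 for IFN-γ in G0, 137 for IFN-γ in G1, 2 for their difference, 83 for genotype, 3 for control ASO, 36 for APOL1 ASO, 7 for APOL1 ASO in G1 with IFN-γ and 18 for the ASO difference of responses. By limma-voom they were in kidney 72 for IFN-γ in G1 and 1 for control ASO and in liver 10 for IFN-γ in G0, 12 for IFN-γ in G1, 48 for control ASO, 68 for APOL1 ASO and 2 for APOL1 ASO in G1 with IFN-γ. With K1 as control ASO the count was in kidney 0 for control ASO, and with K1 as APOL1 ASO in liver 2 for control ASO. The balance of rises and falls turned with some settings. In kidney these were IFN-γ in G0 by DESeq2 (83 up, 122 down) and control ASO with the covariate (582 up, 319 down). In liver they were genotype by DESeq2 (50 up, 34 down) and without shallow libraries (27 up, 16 down), and IFN-γ in G1 by DESeq2 (34 up, 21 down), by limma-voom (11 up, 1 down) and with the covariate (109 up, 28 down). For ASOs in liver they were control ASO by DESeq2 (19 up, 8 down) and limma-voom (39 up, 9 down), and APOL1 ASO by limma-voom (37 up, 31 down) and with the covariate (19 up, 17 down). Of 106 list calls 27 held with an estimated correlation.

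A block for the replicate number, which does not pair the mice, moved none of the 16 counts within a tissue by over 1.5 times (kidney response in G0 48, in G1 38, liver genotype 16), and pairing kidney and liver by animal as a block gave 11 genes for kidney minus liver.

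With each library left out in turn, counts in kidney were 42 to 177 for IFN-γ in G0 (177 without G0 vehicle PBS 3), 27 to 37 for IFN-γ in G1, 0 for their difference, 0 to 5 for genotype (4 without G0 vehicle PBS 2 and 5 without G0 vehicle PBS 3). They were 2 to 21 for control ASO (21 without G0 vehicle PBS 3 and 9 without G1 vehicle PBS 1), 0 to 1 for APOL1 ASO (1 without G0 control ASO PBS 2, G1 APOL1 ASO PBS 2), 0 to 1 for APOL1 ASO in G1 with IFN-γ (0 without G1 APOL1 ASO IFN-γ 1, 3 or 4, G1 control ASO IFN-γ 1, 2 or 3), 0 for the ASO difference of responses. Parentheses name the libraries, by group and replicate, that moved a count by over 1.5 times. Counts in liver were 0 to 1 for IFN-γ in G0 (0 without G0 vehicle IFN-γ 1, 2, 3 or 4 and 1 without G0 vehicle PBS 1, 2, 3 or 4), 1 to 6 for IFN-γ in G1 (1 without G1 vehicle IFN-γ 1, 2 or 4 and 6 without G1 vehicle PBS 1), 0 to 1 for their difference (1 without G1 vehicle PBS 2). For genotype in liver they were 7 to 19 (9 without G0 vehicle PBS 1, 3 or 4 and 7 without G0 vehicle PBS 2 and 10 without G1 vehicle PBS 1 or 4). For ASOs they were 1 to 3 for control ASO (2 without G0 control ASO PBS 3, G0 vehicle IFN-γ 4, G0 vehicle PBS 3, G1 control ASO IFN-γ 1 or 4, G1 vehicle IFN-γ 2, G1 vehicle PBS 4 and 3 without G1 vehicle PBS 1), 6 to 14 for APOL1 ASO (14 without G1 APOL1 ASO PBS 3), 0 to 1 for APOL1 ASO in G1 with IFN-γ (1 without G1 APOL1 ASO IFN-γ 1), 0 for the ASO difference of responses. For kidney minus liver they were 21 to 30. The cause was not tested.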

Other observations

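The contrasts pooled over 6 arms, the test of the hepatocyte share and the tests on Havcr1 and Lcn2 in this part were chosen after the results had been seen. The exceptions are the edgeR values of Havcr1 in the vehicle arm and of Lcn2 over the injury list, whose contrasts were fixed beforehand. The genes of the pooled contrasts were named after their values were seen. Averaged over both genotypes and all dosings (22 PBS and 24 IFN-γ mice), IFN-γ also raised the tubular injury genes Havcr1 (2.16 ± 0.29, adjusted p = 1.28e-06) and Lcn2 (1.89 ± 0.30, 3.03e-05) in kidney. Timp1 (2.49 ± 0.63), an inhibitor of matrix proteases, and mouse Apol10b (1.85 ± 0.29, 1.62e-05) rose too. Macrophage genes rose with them, 9 of 23 markers (camera adjusted p = 1.26e-06 with an estimated correlation). Among them were the complement C1q chains C1qa (0.99 ± 0.14) and C1qb (1.18 ± 0.17) and the monocyte receptor Ccr2 (1.15 ± 0.17). Raised as well was Gzma (2.28 ± 0.35), a granzyme of cytotoxic lymphocytes. Hmox1 (-1.52 ± 0.25) and Scd1 (-0.89 ± 0.15) fell in kidney. In liver the acute-phase genes Saa3 (3.66 ± 0.29, adjusted p = 4.81e-12), Saa1 (2.59 ± 0.38) and Saa2 (2.37 ± 0.40) and the chemokine Cxcl9 (2.75 ± 0.20, 3.12e-13) rose. So did Ubd (3.53 ± 0.36), Gzma (2.44 ± 0.41), the invariant chain Cd74 (1.95 ± 0.23) and Hmox1 (0.94 ± 0.19), with 8 of 24 macrophage markers (camera adjusted p = 0.000674 with an estimated correlation). The pooled difference between tissues was not tested. The edgeR test called 274 genes up and 50 down in kidney and 170 genes up and 27 down in liver, with 68 raised in both tissues, where chance gives 3.03 among 13558 genes tested in both. DESeq2 called 354 genes in liver, where 317 passed without the shallow livers.

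Genotype over the 6 arms (24 G0 and 22 G1 mice) was compared in the same way, and whether it acts differently in liver and kidney was not tested. G1 livers had more Gpnmb (3.81 ± 0.33, adjusted p = 2.75e-11) and Trem2 (2.96 ± 0.46), both expressed by macrophages. They also had more Cx3cr1 (1.47 ± 0.15) and Ccr2 (1.19 ± 0.22) but less Cd163 (-1.10 ± 0.19) and Timd4 (-0.71 ± 0.18). The macrophage list as a whole did not pass camera (3 of 24 genes up and 2 down, median 0.06, adjusted p = 0.494, and 0.778 with an estimated correlation). Collagen genes Col1a1 (0.94 ± 0.15) and Col1a2 (1.08 ± 0.19) were higher, among 10 of 24 fibrosis genes (0.0189 with an estimated correlation). Of 25 cytochrome P450 genes 13 were lower and 2 higher (0.00259), with Cyp2c50 at -3.35 ± 0.25. Lower too were the male-biased genes Elovl3 (-3.73 ± 0.35) and Slco1a1 (-2.94 ± 0.34), the major urinary protein gene Mup1 (-4.11 ± 0.55), whose paralogs share reads, and Scd1 (-2.03 ± 0.32) and Fasn (-1.17 ± 0.25) of fatty acid synthesis. In kidney the histamine-forming enzyme Hdc (1.76 ± 0.20, adjusted p = 1.48e-06), complement C3 (0.74 ± 0.14) and Havcr1 (1.33 ± 0.29, 0.0344) were higher in G1, and the prolactin receptor Prlr (-0.79 ± 0.11) and the transaminase Bcat1 (-1.47 ± 0.22) lower. The edgeR test called 426 genes up and 354 down in liver and 6 genes up and 8 down in kidney. DESeq2 called 676 and 417 in liver and 25 and 41 in kidney.

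The liver genotype difference was weighed against technical explanations. Low depth is argued against by 1088 called genes without the shallow libraries, which were mostly of G1 mice (780 with them, 687 in both). Linkage of most called genes to a transgene on 1 chromosome is argued against by the highest excess of any chromosome, 1.32 times its share of tested genes (chromosome 19). A short linked segment with few genes would not be seen in these shares and stays open, also for Cyp2c50, which lies on chromosome 19. A lower share of hepatocytes alone would raise all other cell types alike, but the fibrosis list rose more than the endothelium list by 0.56 ± 0.11 in mean log2 CPM (fibrosis 0.537 ± 0.129, endothelium -0.024 ± 0.074). In the same scores the hepatocyte list was -0.366 ± 0.11, macrophages -0.009 ± 0.141, T and NK cells 0.323 ± 0.137, B cells 0.452 ± 0.153, neutrophils 0.176 ± 0.174 and red blood cells -0.426 ± 0.143. The APOL1 allele, the transgenic line and the housing or age of each line stay open, since the design does not separate them.

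In kidney the IFN-γ response of Havcr1 over 3 dosing arms was larger in G1 than in G0 by 1.49 on the log2 scale (two-sided permutation p = 0.016, 0.032 adjusted over 2 genes, with 22 G1 and 24 G0 mice). This and the other permutation tests of this paragraph used the log2 of CPM plus a constant, which shrinks differences at low CPM. Havcr1 was low after PBS, so a genotype difference of the same fold under both challenges could also appear as a larger response. The test therefore does not separate a larger response from the scale. In the vehicle arm alone, however, the difference of the responses was -0.26 by edgeR, a value on another scale. After IFN-γ G1 exceeded G0 in Havcr1 by 3.21 with control ASO, 1.37 with vehicle and 0.93 with APOL1 ASO (exact permutation p = 0.0286, 0.0857 and 0.171, and 0.0686, 0.147 and 0.228 adjusted over 12 tests). The response of Lcn2 differed by 0.66 (permutation p = 0.21). Whether APOL1 ASO lowers both genes in G1 mice with IFN-γ stays open with 4 mice per group: against control ASO Lcn2 was -2.19 (exact permutation p = 0.0286, the smallest possible, 0.0686 adjusted over 12 tests, and 0.0466 adjusted over the injury list by edgeR) and Havcr1 -0.91 (exact permutation p = 0.2, 0.24 adjusted). Against vehicle, control ASO was 1.31 for Lcn2 (exact permutation p = 0.0286, 0.0686 adjusted over 12 tests) and 1.49 for Havcr1 (0.0857, 0.147 adjusted), and APOL1 ASO was -0.88 (0.114, 0.171 adjusted) and 0.58 (0.314, 0.343 adjusted), so that a rise with the control ASO stays open as part of the difference. Fewer neutrophils, which also make Lcn2, would lower other neutrophil markers as well. The change of 7 other markers lay above that of Lcn2 by 2.13 ± 0.73. Lcn2 was singled out after its fall was seen, which can widen this gap, so the comparison does not decide on neutrophils. A weaker IFN-γ response is argued against by a median of 0.34 of the IFN-γ list. The amount of APOL1 RNA left, which the counted transcripts do not include, stays open too.

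The mouse of uncertain dosing (code K1, G1, PBS) had 50.2 CPM of Csad in liver, where G1 PBS livers with control ASO had 110.2 to 463 (n = 3) and those with APOL1 ASO 47.5 to 131 (n = 3). Its kidney had 181 CPM of Csad, 2.06 of Havcr1, 0.551 of Lcn2 and a summed 344 of the IFN-γ list, where 22 kidneys after PBS had 254 to 540.3. Its kidney Csad, Lcn2 and IFN-γ sum lay below the G1 PBS mice with control ASO (from 194.9, 1.043 and 395.9) and within the range of those with APOL1 ASO. Its Havcr1 lay within the range with control ASO (0.596 to 4.346) and above that with APOL1 ASO (0.9562 to 1.974). The sum in its liver was 973 CPM, where livers after PBS had 749.6 to 1686, and lay below both G1 PBS groups (1096 to 1208 with control ASO, 1260 to 1439 with APOL1 ASO). With 3 mice per group these values do not settle its dosing. CPM in this paragraph were normalised over all libraries of a tissue, this mouse included and without the low-count filter, so that they differ somewhat from CPM elsewhere.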
